A study of Homo sapiens with 23 samples.

How the data were processed

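RNA of MCF7 cells, an estrogen receptor-positive luminal breast cancer line, was measured by MARS-seq, which counts tags near the 3′ ends of transcripts. Per the labels, 30 ng of input RNA was used, and cells with p53 (WT) or with p53 knocked out (KO) were left untreated (NT) or treated with 5 µM tamoxifen for 48 h, while other WT cells received 5 µM Nutlin for 24 h. Per the submitters' processing notes, cutadapt, STAR 2.4.2a, HTSeq and DESeq2 were used with the genome build hg38. The annotation, the filters, the strand and the handling of reads with several matches are not stated.

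The deposited tables hold counts per gene and library, read from their headers and from their whole-number values. One table covers the 6 libraries of the Nutlin set (10339 genes) and another the 17 libraries of the tamoxifen set (12175 genes), whose name says that they are counts of unique molecular identifiers; for the Nutlin table this is not stated. The smallest total of any gene was 7 counts in the former and 6 in the latter, and no gene with fewer counts is listed. The authors' comparisons in the same tables are log2 fold changes of the group named first over the group named second. The authors' p-value columns hold p-values and adjusted p-values between 0 and 1. These deposited comparisons were used only beside the counts recomputed here, with the sign of the fold change reversed so that it gives treated over untreated or KO over WT.

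Libraries of the tamoxifen set carry the series letters EA or ED in their names, and 5 pairs share a name stem, with a date added to the name of 1 of the 2 libraries. Libraries sharing a stem were summed, since they may come from 1 RNA sample, which gave 12 units, 3 in each of 4 groups. The units are called a and b (series EA) and D (series ED). The Nutlin set had 3 libraries in each of 2 groups, each taken as a unit. The counts of both libraries of a stem pair differed by more than sampling noise, with a chi-square per degree of freedom of 4.71 to 13.2, against 4.94 to 30.1 for other pairs of the same group. Libraries of units a and D were closer than a stem pair in untreated WT (7.71 against 13.2 for a), untreated KO (5.44 against 8.3 for b) and treated KO (4.94 against 8.71 for b). The treated WT pair (8.35) and the untreated WT pair of b (4.71) were the closest of their groups. The counts thus do not show that a stem pair comes from 1 RNA sample. The labels do not say whether replicates are separate cultures, so the p-values measure a spread between samples that may be technical only.

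Genes were filtered with filterByExpr, libraries were scaled by TMM, and groups were compared with the quasi-likelihood F test of edgeR 4.0.16 (with limma 3.58.1, in R 4.3.3), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The 12 units were fitted together with the series as a covariate, and the Nutlin set was fitted apart. The run, as read from the dates in the names, was not in this fit and is not balanced over groups. The treated WT unit a is dated only, and the untreated and treated KO units a are undated only. An effect of the run would therefore be partly mixed with p53 status and tamoxifen. The comparisons were KO against WT in untreated cells and under tamoxifen, tamoxifen against untreated in WT and in KO, the difference of the tamoxifen response between KO and WT (the interaction term), and Nutlin against untreated in WT. Normalised read counts are edgeR's CPM with TMM scaling, and means are given with the SD over 3 units. Log2 fold changes are those of the edgeR fit, and an SE beside one is the SE of that fit. Intervals for single ratios are exact 95% intervals for counts, and a group at 0 was set to a floor of 3 counts over the group. These intervals and floors cover counting error only.

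The genes named by rule were TP53, CDKN1A, MDM2, ESR1 and GATA3 in every comparison, whether or not they passed. To these were added the 6 higher and 6 lower passing genes with the largest fold change, a mean of at least 10 CPM in the higher group and no overlap between units, and the 2 passing members with the smallest p of each list with at least 2 passing members. Members of small counts named beyond the rule were chosen after their values were seen. Gene positions are those of GENCODE 29 on hg38. Several named genes have close copies (SNAR-H, LCE1B, MUC3A, TNFRSF10C, IFIT3 and the OAS genes), and reads shared between copies were not tested for.

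17 gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. Lists with fewer than 3 tested genes were not tested. Members that passed were counted with the adjustment over all genes and adjusted over the list alone. Some lists share members, such as SESN2 in the p53 and integrated stress response lists and UHRF1 in the DNA replication and chromatin lists. Genes called higher or lower with Nutlin were tested as sets in the other comparisons, and log2 fold changes were compared across genes by rank correlation, for pairs of comparisons that share no library. The SE of these correlations is a jackknife over units. Genes are not independent replicates.

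The samples, comparisons, lists, named-genes rule and most alternatives were fixed before the data were examined. Those alternatives were DESeq2's size factors in edgeR (RLE), DESeq2 1.42.0, no filter on low counts, no series covariate, a replicate block, all 17 libraries (with the run as a covariate, with a block by replicate number, or with limma-voom and the name stem as a random block), series EA alone, the groups of a comparison alone, and each unit left out in turn. Chosen after the data were seen were the fit without the untreated WT unit b together with the block, its use in the list and set tests, the removal of the library with the fewest counts, and the leave-one-out of the correlations. A change of pseudocount was not applicable, since the fits use counts.

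Whether the letters pair the units was checked from the correlation of same-letter deviations from the group means. It was 0.53, 0.805 and 0.596 for tamoxifen in KO and 0.249, 0.767 and 0.351 for KO under tamoxifen, and blocked values are given beside these comparisons. For Nutlin it was -0.083, 0.00119 and -0.0587, for KO in untreated cells -0.112, 0.247 and 0.264, and for tamoxifen in WT 0.075, 0.224 and 0.42, and the letters were not taken to pair these units. Between different letters the values for tamoxifen in WT were -0.299 to 0.0737. Genes such as EGR1 and FOS were low in the b units of all 4 groups. An effect of the letter therefore stays possible there too, and the series covariate, which joins a and b, does not remove it. With the block, 106 genes were called for KO in untreated cells (59 without) and 243 for tamoxifen in WT (78 without).

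The steps were tested on simulated data made from these counts, with 200 genes changed. The changed genes were drawn from those with a mean of at least 20 CPM. No effect of series or letter and no unit set apart from the others was simulated. The shares recovered therefore do not cover genes of fewer counts or such effects. For KO against WT in untreated cells, edgeR recovered 66% of the genes changed 2-fold and 99% of those changed 4-fold, for tamoxifen in KO 73% and 99%, and for the interaction 19% and 96%. For Nutlin 96% and 100% were recovered. Of the genes edgeR called in these 4 simulations, 5 of 170, 5 of 177, 5 of 120 and 12 of 208 were false. For tamoxifen in WT 8 of 176 were false, and for KO under tamoxifen 15 of 187. Groups with no change gave 1 call.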

Results

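RNA was counted in 23 MARS-seq libraries of MCF7 breast cancer cells. In the Nutlin set, cells with p53 (WT) were untreated (3 libraries) or treated for 24 h with 5 µM Nutlin (3 libraries), a compound that blocks the binding of MDM2 to p53. In the tamoxifen set, WT cells (5 untreated and 4 treated libraries) and p53 knockout (KO) cells (4 and 4) received 5 µM tamoxifen, an estrogen receptor modulator, for 48 h. The Nutlin-set libraries held 1275736 to 1970707 counts. Of the 17 tamoxifen-set libraries, 15 held 1652694 to 3948153 counts, and the untreated WT libraries labelled replicates 3 and 4 held 890253 and 129204. Both make up the untreated WT unit b, whose 1019457 counts were the fewest of the 12 units (up to 7491138), and which was less like the other units (mean correlation 0.880) than any other unit was (at least 0.945). For this reason, values without unit b are given beside the numbers of called genes and beside several lists, sets and named genes.

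**Figure D1:**
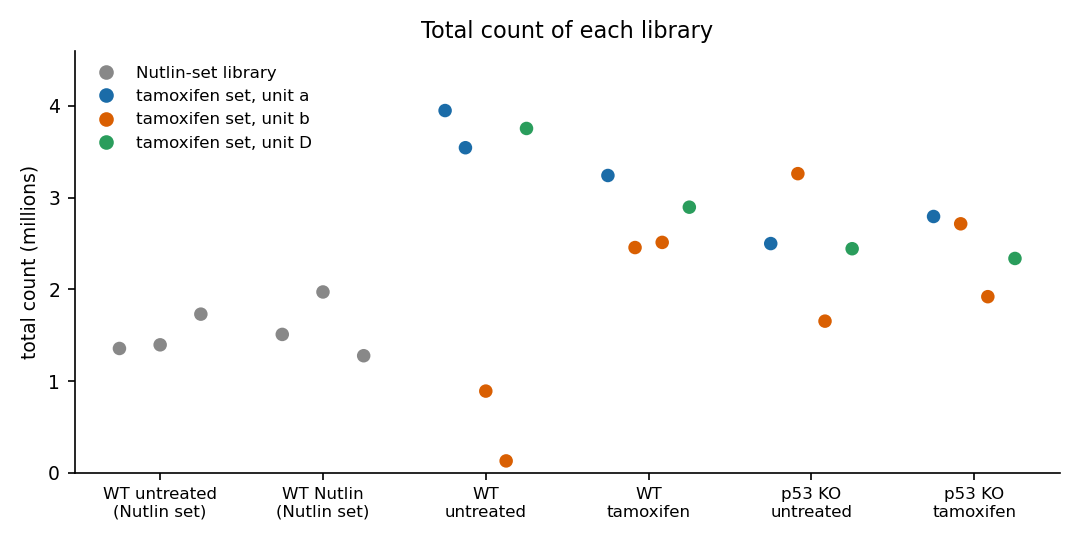
Total count of each of the 23 libraries (points), by group and coloured by unit letter. Untreated WT replicate 4, at 129204 counts, and replicate 3, at 890253, lie below all the other libraries.

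The level of TP53 mRNA was compared with the labels first. TP53 lies on chromosome 17 at 7661779 to 7687550 (GENCODE 29 on hg38, minus strand). TP53 measured 132.7, 79.8 and 149.7 CPM in the untreated WT units a, b and D and 55.6, 43.6 and 40.3 CPM in the untreated KO units. Under tamoxifen it measured 110.1, 81.1 and 103.9 CPM in WT and 40.0, 27.2 and 28.7 CPM in KO. Every KO unit was below every WT unit. Tags near the 3′ end do not test the edit itself, and the KO cells kept TP53 tags. In the library labelled untreated WT replicate 4, TP53 had 6 counts, or 44.0 CPM (exact 95% interval 16.2 to 95.9), which is inside the range of the untreated KO libraries (41.3 to 56.9), while the interval also takes in the lowest value of the treated WT libraries (76.4). CDKN1A in that library had 21 counts, or 154 CPM (95.4 to 236), below every other WT library (at least 372). This level lay between the untreated (74.2 to 122) and the treated KO libraries (160 to 231), and its interval takes in values of both.

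Nutlin against untreated WT cells asks which genes respond when p53 is released from MDM2. CDKN1A, a cyclin-dependent kinase inhibitor on chromosome 6 (36676460 to 36687339), rose from 543 ± 48.4 to 19390 ± 880 CPM (SD, n = 3), a 35.7-fold change (log2 5.16, SE 0.0577, edgeR adjusted p = 1.2e-32). MDM2, the ubiquitin ligase of p53 on chromosome 12 (68808176 to 68850686), rose 50.7-fold from 11.1 ± 6.51 to 588 ± 33.5 CPM (edgeR adjusted p = 7.5e-23). GDF15, a secreted stress cytokine, rose 9.68-fold from 1171 ± 35.0 CPM. TP53 itself fell 2.73-fold, from 132 ± 10.0 to 48.2 ± 4.13 CPM (edgeR adjusted p = 1.7e-11). Of 31 p53 targets tested, 30 rose and 0 fell, also when adjusted over the list alone; FUCA1, a lysosomal fucosidase, did not pass (log2 0.21, edgeR adjusted p = 0.399). The median log2 change of the p53 targets was 1.92 (camera adjusted p = 8.1e-56, and 0.00727 with an estimated correlation).

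Genes of the cell cycle fell with Nutlin. All 31 tested G2/M genes fell, with a median log2 change of -4.63 that was the same with the 1 gene at 0 set to its bound (camera adjusted p = 1.4e-50, and 0.0230 with an estimated correlation). Among them, UBE2C, a ubiquitin-conjugating enzyme of mitosis, was 47.0-fold lower and CDC20, an activator of the anaphase-promoting complex, 36.9-fold lower. Of 28 DNA replication genes, 27 fell, with a median of -3.26 (camera adjusted p = 3.8e-36, and 0.0230 with an estimated correlation). TK1, a thymidine kinase, was 33.2-fold lower and MCM7, a subunit of the replicative helicase, 9.77-fold lower. PCNA, the replication clamp, did not pass (log2 -0.05, edgeR adjusted p = 0.681). UHRF1 was 30.9-fold lower and DNMT1 2.63-fold lower; both maintain DNA methylation. The list of chromatin and DNA methylation regulators as a whole went both ways, with 5 of 28 genes higher (KMT2B, KDM6B, NSD1, SMARCA4 and KDM5C, by log2 0.31 to 1.07, named after their values were seen) and 9 lower (median -0.01, camera adjusted p = 0.206).

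Among the genes with the largest changes, LCE1B and KANK3 had 0 counts in untreated cells and were at least 25-fold and 24.3-fold higher with Nutlin (floor of 3 counts over the group). SUGCT (1 count untreated and 148 with Nutlin) had a ratio of 144 (exact 95% interval 25.4 to 5720), LINC01164 (2 and 204) one of 99.2 (27.1 to 825) and ADAMTS7 (2 and 154) one of 74.9 (20.4 to 624). SERPINF1, a secreted serpin that inhibits angiogenesis, rose 63.3-fold from 1.78 ± 0.339 to 118 ± 14.8 CPM (n = 3). RAD54L, HJURP, SPC25 and CIT, which act in recombination, at centromeres and in cytokinesis, had 0 counts with Nutlin and were at least 49.7-, 47.6-, 44.2- and 23.7-fold lower. CDC45, of the replicative helicase, was 72.2-fold lower (99.1 ± 3.54 to 1.19 ± 0.772 CPM) and CENPF, of the kinetochore, 64.9-fold lower.

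Genes of cholesterol synthesis were higher with Nutlin. Of 24 cholesterol synthesis genes, 18 rose and 1 (EBP, log2 -1.32, named after its value was seen) fell (19 and 1 adjusted over the list alone), with LDLR, the LDL receptor, 4.02-fold and TM7SF2, a sterol reductase, 2.5-fold higher (median 0.76, camera adjusted p = 7.2e-06, and 0.0230 with an estimated correlation). Of 28 lysosome genes, 16 rose and 2 fell (GLA and CTSZ, log2 -2.04 and -1.27, named after their values were seen; 18 and 2 adjusted over the list alone), with the autophagy receptor SQSTM1 2.33-fold and the protease CTSL 2.10-fold higher (median 0.47, camera adjusted p = 0.00322, adjusted p = 0.0912 with an estimated correlation). Of 10 basal and mesenchymal genes, 6 rose, among them the actin ACTA2, 18.8-fold from 14.9 ± 2.41 CPM, and fibronectin FN1, 1.68-fold (median 0.63, camera adjusted p = 0.00888, adjusted p = 0.0912 with an estimated correlation). GATA3, a luminal transcription factor on chromosome 10 (8045378 to 8075203), rose 1.16-fold from 1114 ± 39.8 to 1293 ± 21.4 CPM (edgeR adjusted p = 0.0014). The luminal list went both ways, with 12 of 26 genes higher and 7 lower (13 and 7 adjusted over the list alone; median 0.16, camera adjusted p = 0.491), and CLDN4, a tight junction protein, and KRT19, a keratin, rose 2.51-fold and 1.82-fold. ESR1, the estrogen receptor on chromosome 6 (151656691 to 152129619), was too low to test, with 1.72 to 6.34 CPM in untreated libraries and 0 to 4.08 with Nutlin.

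The other lists did not pass as sets with Nutlin; where no other count is given, that adjusted over the list alone was the same. Small counts of a direction are named after their values were seen. Of 26 estrogen receptor targets 8 rose and 10 fell (median -0.08, camera adjusted p = 0.463), with the growth factor AREG 1.94-fold higher and the secreted protein OLFM1 3.77-fold lower. Of 21 interferon-response genes 10 rose and 1 (IFITM2, log2 -0.25) fell, with a median of 0.41 (camera adjusted p = 0.0646), TAP1, a peptide transporter, 3.51-fold higher and ISG15, a ubiquitin-like protein, 1.74-fold higher. Of 21 integrated stress response genes 9 rose and 8 fell (median -0.10, mean 0.11, camera adjusted p = 0.516), with GADD45A and SESN2, also p53 targets, 6.82-fold and 2.45-fold higher. Of 17 unfolded protein response genes 8 rose and 2 fell (median 0.21, camera adjusted p = 0.206), with EDEM1 (log2 1.37) and the chaperone CALR (log2 0.49) higher and PDIA6 (log2 -0.20) and SDF2L1 (log2 -0.29) lower. Of 17 hypoxia and glycolysis genes 7 rose and 4 fell (median 0.30, camera adjusted p = 0.491), with the glucose transporter SLC2A1 2.45-fold higher and TPI1 (log2 -0.84), LDHA (-0.65), GAPDH (-0.28) and PKM (-0.16) lower. Of 31 ribosomal protein genes 2 rose and 8 fell (2 and 6 adjusted over the list alone; median -0.05, camera adjusted p = 0.571), among the latter RPL8 (log2 -0.39) and RPLP0 (log2 -0.30), while RPL37 (log2 0.66) and RPL3 (log2 0.30) rose.

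With Nutlin, edgeR called 4213 of 7803 genes (2130 higher and 2083 lower), of which 769 were at least 2-fold higher and 785 at least 2-fold lower. DESeq2 called 3325. The libraries of both groups did not overlap for 58.7% of genes, against 10% by chance. Leaving out 1 library gave 3702 to 4057 calls, and the authors' deposited comparison held 3318, of which 3107 were among the 4213, all in the same direction.

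KO against WT in untreated cells asks what differs with loss of p53. The labels name no second KO clone and no rescue. Other differences between the KO and WT cells therefore cannot be told apart from loss of p53. CDKN1A fell 4.72-fold, from 477 ± 97.8 CPM in WT to 102 ± 20.3 in KO (SD, n = 3; log2 -2.24, SE 0.25, edgeR adjusted p = 0.000444). TP53 fell 2.64-fold, from 121 ± 36.4 to 46.5 ± 8.04 CPM (log2 -1.40, SE 0.249, edgeR adjusted p = 0.0141). FDXR, a mitochondrial reductase on chromosome 17 (74862497 to 74873031), fell 2.85-fold (edgeR adjusted p = 0.00828). Of 29 p53 targets tested, 4 fell and 0 rose (11 and 0 adjusted over the list alone), CDKN1A, FDXR and, named after their values were seen, PHLDA3 (log2 -1.10) and BTG2 (log2 -1.05). The median of the p53 targets was -0.45 (camera adjusted p = 2.0e-12, and 0.00101 with an estimated correlation; 8.0e-19 without the untreated WT unit b). MDM2 did not pass (log2 -1.08, SE 0.356, edgeR adjusted p = 0.293), nor did ESR1 (log2 -0.67, edgeR adjusted p = 0.626) or GATA3 (1254 ± 104 and 1214 ± 127 CPM; log2 -0.05, edgeR adjusted p = 0.957).

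Further genes lower in untreated KO cells were TNFRSF10C, a decoy receptor for TRAIL on chromosome 8 (23102590 to 23117437), at 16.4 ± 8.50 CPM in WT and 1.53 ± 0.911 in KO (8.55-fold lower, edgeR adjusted p = 0.00436), and KLK11, a kallikrein protease on chromosome 19 (51022216 to 51028039), at 21 ± 3.63 and 3.74 ± 1.97 CPM (5.56-fold, edgeR adjusted p = 0.00163). ENTPD8, a nucleotidase, was 8.17-fold lower (16.2 ± 15.9 and 1.40 ± 0.691 CPM), with a log2 of -3.03 that was -2.24 without the untreated WT unit b. SMIM5 was 6.10-fold lower, CYSRT1 5.16-fold and PSCA, a membrane antigen, 5.14-fold (log2 -2.36, and -1.65 without unit b). Higher in KO were SLC7A5, the amino acid transporter on chromosome 16 (87830023 to 87869488), at 820 ± 235 CPM in WT and 1967 ± 258 in KO (2.45-fold, edgeR adjusted p = 0.00864), and WNT6, a Wnt ligand, 5.62-fold (edgeR adjusted p = 0.00436). METTL7A, a methyltransferase, was 3.51-fold higher, SCIN, an actin-severing protein, 3.24-fold, CXCL12, a chemokine and estrogen receptor target, 2.69-fold, and AMFR, a ubiquitin ligase, 2.25-fold.

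Several lists shifted by small amounts in untreated KO cells with 0 single members called over all genes, and their calls were lost with an estimated correlation. The medians were 0.23 for G2/M genes (camera adjusted p = 6.9e-05, adjusted p = 0.339 with an estimated correlation), 0.30 for DNA replication (2.3e-05; 0.339; median 0.19 without the untreated WT unit b) with 1 gene higher adjusted over the list alone, and 0.31 for the integrated stress response (0.00044; 0.339) with 2. The same held for chromatin regulators (median 0.14, 1 gene higher adjusted over the list alone, 0.0387, adjusted p = 0.421 with an estimated correlation), which also lost the call without the untreated WT unit b (median 0.06, 0.304), and for 3 fibroblast markers (median 0.32, 1 gene higher adjusted over the list alone, 0.0387, adjusted p = 0.339 with an estimated correlation). In the untreated WT unit b the G2/M genes lay 0.873 log2 units lower than in the other units of its group (difference -0.873), and the DNA replication genes 0.477 lower (difference -0.477). The luminal list did not pass (median -0.10, camera adjusted p = 0.114), with 2 genes lower adjusted over the list alone. Without that unit it passed at the preset correlation (0.0408), while with an estimated correlation and all units the adjusted p was 0.403. Estrogen receptor targets (2 higher, CXCL12 and SLC7A5; 3 higher and 6 lower adjusted over the list alone; median 0.06, and -0.13 without unit b, 0.527) and interferon genes (2 lower adjusted over the list alone; median -0.17, 0.0965) did not pass. Basal genes (1 lower, ACTA2, log2 -2.28, named after its value was seen; median -0.03, 0.921), cholesterol synthesis (1 lower adjusted over the list alone; -0.04, and 0.15 without unit b, 0.859), unfolded protein response (0.19, 0.186), lysosome (-0.10, and 0.14 without unit b, 0.921), hypoxia and glycolysis (median 0.00, mean -0.03, 0.921) and ribosomal proteins (-0.14, and 0.01 without unit b, 0.114) did not pass either.

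In untreated cells edgeR called 59 of 10037 genes between KO and WT (8 higher and 51 lower; 989 at an unadjusted p under 0.05). DESeq2 called 125, limma-voom 36, and the authors' deposited comparison 198, which held all 59 in the same direction. The units did not overlap for 13.1% of genes, against 10% by chance. Without the untreated WT unit b there were 94 calls (26 higher and 68 lower, 57 of the 59 kept), and without the untreated KO units a, b and D there were 22, 12 and 11. Leaving out 1 unit ended the call of 11 of the 15 named genes at least once. That of TP53 ended without the untreated WT unit D (edgeR adjusted p = 0.101) and without the untreated KO units b (0.116) and D (0.158), while CDKN1A passed in every such fit.

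Tamoxifen against untreated WT cells asks for the response in the presence of p53. GREB1, an estrogen receptor cofactor and target on chromosome 2 (11482341 to 11642788), fell 11.3-fold, from 161 ± 79.9 to 14.5 ± 3.52 CPM (SD, n = 3; log2 -3.50, SE 0.384, edgeR adjusted p = 0.00036). TFF1, a secreted trefoil peptide on chromosome 21 (42362282 to 42366594), fell 4.69-fold, from 17646 ± 10472 to 3688 ± 797 CPM (log2 -2.23, SE 0.271, edgeR adjusted p = 0.000666), and CXCL12 fell 4.84-fold. Also lower were CYP2T1P, a pseudogene (8.33-fold), SNAR-H, a small noncoding RNA (7.82-fold), and the transcription factor SOX3 (5.94-fold). Estrogen receptor targets had 3 of 31 genes lower and 0 higher (11 and 0 adjusted over the list alone), GREB1, TFF1 and CXCL12, with a median of -0.39 (camera adjusted p = 1.2e-08, adjusted p = 0.0531 with an estimated correlation), and 11 lower without the untreated WT unit b.

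Among the genes higher with tamoxifen in WT cells, BCAS1, a gene of the 20q13 amplicon on chromosome 20 (53936777 to 54070594), rose 3.42-fold from 70.7 ± 13.1 to 236 ± 45.7 CPM (edgeR adjusted p = 0.000666). OAS1, an antiviral oligoadenylate synthetase on chromosome 12 (112906777 to 112933222), rose 3.21-fold from 10.8 ± 2.08 to 33.2 ± 7.35 CPM (edgeR adjusted p = 0.0113). Interferon genes had 5 of 30 higher and 0 lower (18 and 0 adjusted over the list alone), with a median of 0.82 (camera adjusted p = 3.9e-15, adjusted p = 0.0531 with an estimated correlation), and 12 higher without the untreated WT unit b. They were OAS1, IFITM1 (2.98-fold, edgeR adjusted p = 0.048), IFIT3 (3.35-fold, 0.0496) and, named after their values were seen, IRF9 (log2 1.22) and PSMB9 (log2 1.13). With RLE scaling IFIT3 and IFITM1 no longer passed (edgeR adjusted p = 0.0510 and 0.0502). The same held without the series covariate (0.144 and 0.0543) and with limma-voom (limma-voom adjusted p = 0.190 and 0.0665). With 1 unit left out, IFIT3 passed only without the untreated WT unit b, and IFITM1 failed in several of these fits. GABBR2, a GABA receptor subunit, was 3.96-fold higher, HSD17B14, a steroid dehydrogenase, 3.68-fold, and the lectin CD22 3.34-fold.

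Luminal genes went both ways in WT cells, with AGR2, a disulfide isomerase, 2.27-fold higher (edgeR adjusted p = 0.016) and TFF3 2.32-fold lower (0.029); 2 were higher and 2 lower adjusted over the list alone, and the list did not pass (median 0.20, camera adjusted p = 0.0778). CDKN1A (log2 0.34, edgeR adjusted p = 0.505), MDM2 (-0.29, 0.71), TP53 (-0.32, 0.542), ESR1 (-0.48, 0.608) and GATA3 (0.21, 0.588) did not pass, nor did the p53 targets (median 0.16, camera adjusted p = 0.522). G2/M genes were lower (median -0.47, 0 called and 12 adjusted over the list alone; camera adjusted p = 2.8e-08, adjusted p = 0.186 with an estimated correlation), with 10 called without the untreated WT unit b. Lysosome genes were higher (median 0.45, 1 called, NPC2, a cholesterol carrier, log2 1.10, named after its value was seen; 9 adjusted over the list alone, and 5 called without unit b; 2.5e-08, adjusted p = 0.285 with an estimated correlation). In every b unit the lysosome genes lay 0.508 to 0.664 log2 units higher than in the other units of its group, and the interferon genes 0.361 to 0.419. Ribosomal protein genes were lower (median -0.27, 3 adjusted over the list alone; 2.1e-05, adjusted p = 0.285 with an estimated correlation) and cholesterol synthesis genes higher (0.24, 0 called, 0.0464, adjusted p = 0.658 with an estimated correlation). Without unit b the cholesterol synthesis median was 0.42 (camera adjusted p = 0.000109, 3 called). DNA replication (median -0.11, 0.296, and 0.00096 without unit b), basal (0.20, 0.385), integrated stress response (0.01, mean -0.08, 0.522), unfolded protein response (0.03, 0.415), hypoxia and glycolysis (-0.20, 0.47), chromatin (0.05, mean -0.02, median -0.06 without unit b, 0.522) and fibroblast (1 higher adjusted over the list alone, 0.77, 0.131) lists did not pass. With an estimated correlation and all units, DNA replication had a camera adjusted p of 0.752.

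In WT cells edgeR called 78 of 10037 genes with tamoxifen (50 higher and 28 lower; 1564 at an unadjusted p under 0.05), DESeq2 284 and limma-voom 51. The deposited comparison held 497, with 75 of the 78. The units did not overlap for 17.6% of genes, against 10% by chance. Without the untreated WT unit b there were 491 calls (277 higher and 214 lower, all 78 kept). Without the untreated WT unit a there were 57 (20 higher and 37 lower, 33 of the 78 kept), and without the untreated WT unit D 20 (7 higher and 13 lower). The majority of calls was thus lower in these last fits. Without the treated WT units a, b and D there were 28, 14 and 10, without the untreated KO units a and D 46 and 41, and without the treated KO units b and D 49 and 42. Of 15 named calls 10 ended in at least 1 of these fits, while GREB1, TFF1 and BCAS1 were among those that did not.

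Tamoxifen against untreated KO cells asks for the response without p53. GREB1 fell 10.4-fold, from 257 ± 7.87 to 24.1 ± 10.6 CPM (SD, n = 3; log2 -3.38, edgeR adjusted p = 0.000268), TFF1 4.40-fold, from 9499 ± 3135 to 2120 ± 489 CPM (edgeR adjusted p = 0.000805), and CXCL12 5.00-fold. BCAS1 rose 6.79-fold, from 22.3 ± 4.92 to 153 ± 13.3 CPM (log2 2.76, SE 0.233, edgeR adjusted p = 1.6e-05). OAS1 rose 4.88-fold to 34.7 ± 10.5 CPM (edgeR adjusted p = 0.000805). OASL, an antiviral protein, rose 6.60-fold, IFI27 6.08-fold, IFIT3 5.74-fold, the chemokine CCL5 5.23-fold and PLEKHS1 6.16-fold. Lower were SOX3 (6.55-fold), the protease TMPRSS3 (6.39-fold), the transcription factor GATA4 (4.56-fold) and ACOX2, a peroxisomal oxidase (4.55-fold). CDKN1A (102 ± 20.3 and 196 ± 32.8 CPM, 1.92-fold) had an edgeR adjusted p of 0.0735; it passed with a replicate block (0.00308) and without the untreated WT units a (0.0461) or b (0.016).

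Of 30 interferon genes, 9 rose and 0 fell in KO cells (23 and 0 adjusted over the list alone, 12 and 0 with a replicate block, 14 and 0 without the untreated WT unit b), with a median of 0.97 (camera adjusted p = 8.8e-27, and 0.00642 with an estimated correlation). Of 31 estrogen receptor targets 3 fell and 0 rose, GREB1, TFF1 and CXCL12 (11 lower and 2 higher adjusted over the list alone, 5 and 1 with the block, 8 and 2 without unit b), with a median of -0.56 (8.4e-13, and 0.0103 with an estimated correlation). G2/M genes were lower (median -0.43, 0 called and 2 adjusted over the list alone; camera adjusted p = 5.1e-10, adjusted p = 0.064 with an estimated correlation), with 2 called with the block and 9 without unit b. Lysosome genes were higher (median 0.47, 1 called, SQSTM1, log2 1.02, named after its value was seen; 5 adjusted over the list alone, 4 called with the block and 3 without unit b; 3.9e-07, adjusted p = 0.321 with an estimated correlation). The luminal list was higher (median 0.23, 0.00687, adjusted p = 0.11 with an estimated correlation), with AGR2 2.69-fold higher, CLDN4 1.77-fold higher (edgeR adjusted p = 0.0307), TFF3 lower (log2 -1.05, named after its value was seen), and 5 higher and 1 lower adjusted over the list alone and with the block, against 4 and 1 without unit b. The p53 targets were higher (median 0.20, 0.0094, adjusted p = 0.064 with an estimated correlation), with PLK2, a kinase, called (log2 1.45, named after its value was seen) and 4 higher adjusted over the list alone. With the block 3 p53 targets were called higher, CDKN1A among them, and 4 without unit b. Cholesterol synthesis (median 0.20, 0.0142, adjusted p = 0.642 with an estimated correlation; 2 higher adjusted over the list alone and with the block, 3 without unit b), ribosomal protein (-0.17, 0.00542, adjusted p = 0.52 with an estimated correlation) and DNA replication genes (-0.19, 0.0209, adjusted p = 0.642 with an estimated correlation) also passed at the preset correlation alone. Basal (median 0.01, mean -0.09, median 0.17 without unit b, 0.835), integrated stress response (-0.07, 0.756), unfolded protein response (0.01, lower by camera, 0.835), hypoxia and glycolysis (0.10, 0.835), chromatin (-0.03, 0.585) and fibroblast (0.41, 0.756) lists did not pass, nor did TP53 (log2 -0.54, edgeR adjusted p = 0.39), MDM2 (-0.29), ESR1 (-0.08) or GATA3 (0.43, 0.299). Without unit b and with the block, TP53 (0.0133) and GATA3 (0.00615) passed.

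In KO cells edgeR called 140 of 10037 genes with tamoxifen (107 higher and 33 lower; 1272 at an unadjusted p under 0.05), DESeq2 260, limma-voom 95 and edgeR with a replicate block 286 (206 higher and 80 lower). The deposited comparison held 260, with 135 of the 140. The units did not overlap for 22% of genes, against 10% by chance. Without the untreated WT unit b there were 462 calls (273 higher and 189 lower, all 140 kept), and without the treated WT unit D 64. Without the untreated KO units a, b and D there were 38, 61 and 24, and without the treated KO units a, b and D 72, 41 and 20. Of 16 named calls 5 ended in at least 1 of these fits.

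**Figure D2:**
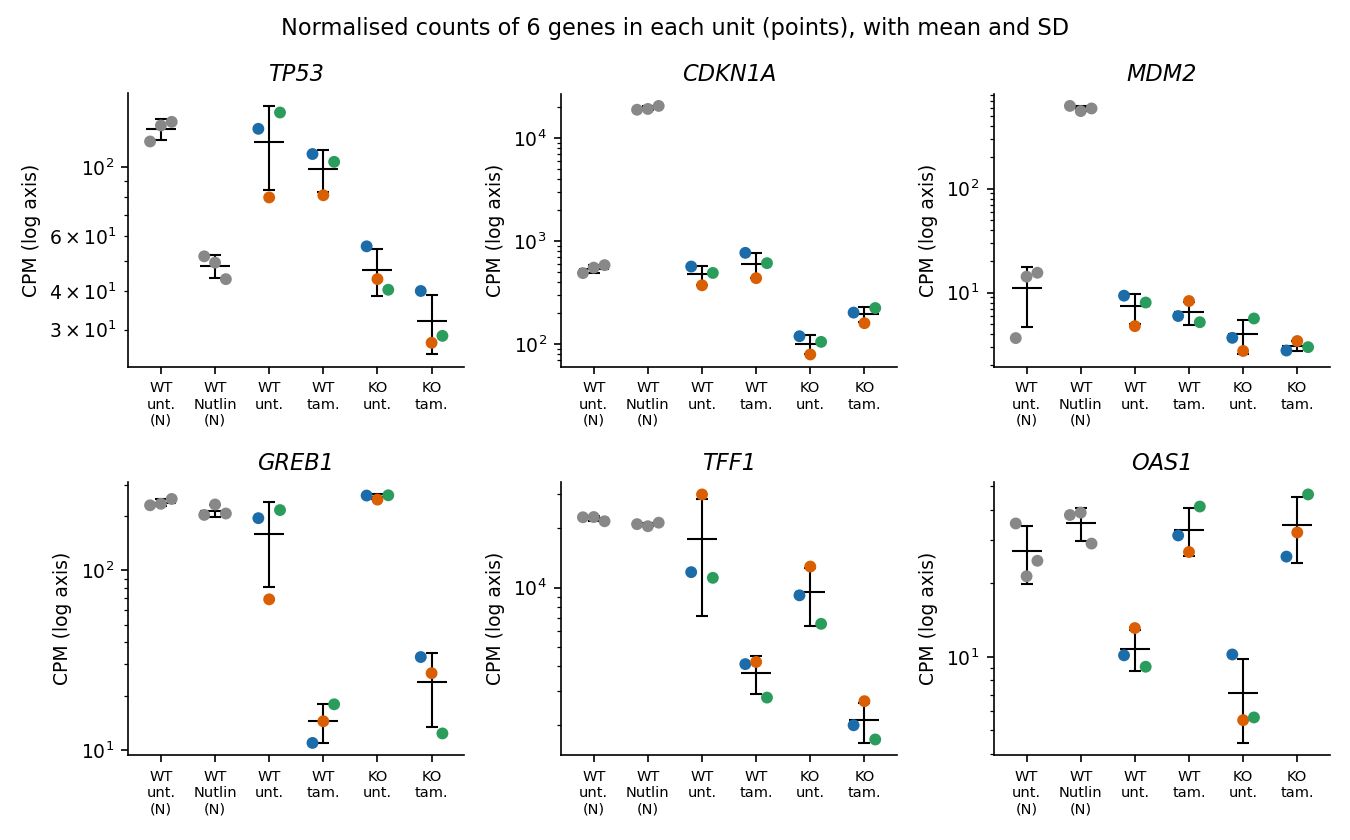
Normalised read counts (CPM, log axes) of TP53, CDKN1A, MDM2, GREB1, TFF1 and OAS1 in each unit (points; grey for the Nutlin set, marked N, blue for a, orange for b, green for D), with the mean and SD of each group of 3. CDKN1A rises from 543 to 19390 CPM with Nutlin and falls from 477 to 102 CPM between untreated WT and KO cells, while GREB1 and TFF1 fall with tamoxifen in both.

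KO against WT under tamoxifen asks what differs with loss of p53 in treated cells, with the same limit as in untreated cells. CDKN1A fell 3.11-fold, from 606 ± 166 CPM in WT to 196 ± 32.8 in KO (SD, n = 3; log2 -1.64, SE 0.243, edgeR adjusted p = 0.00283), and TP53 3.08-fold, from 98.4 ± 15.3 to 32.0 ± 6.97 CPM (edgeR adjusted p = 0.0045). TNFRSF10C fell 19.2-fold, from 18.1 ± 3.45 to 0.770 ± 0.810 CPM (10 counts over the treated KO units; edgeR adjusted p = 0.000712), and ACTA2 9.37-fold (0.000712). KLK11 was 5.05-fold lower, CYSRT1 4.90-fold, and the mucins MUC3A and MUC20 4.87-fold and 4.85-fold. Higher in KO were FOSL1, an AP-1 transcription factor, 5.62-fold from 5.39 to 31.3 ± 8.63 CPM (edgeR adjusted p = 0.000967), SCIN 4.73-fold to 103 ± 25.3 CPM, CCL5 5.64-fold, WNT6 5.41-fold, PLEKHS1 4.17-fold and CLEC3A, a lectin, 2.94-fold. MDM2 (log2 -1.08, edgeR adjusted p = 0.307), ESR1 (-0.28) and GATA3 (0.18, 0.87) did not pass.

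Under tamoxifen, 1 of 29 p53 targets fell in KO and 0 rose, CDKN1A (8 and 0 adjusted over the list alone, 3 and 0 with a replicate block, 5 and 0 without the untreated WT unit b), with a median of -0.26 (camera adjusted p = 2.1e-07, and 0.00538 with an estimated correlation). G2/M genes (median 0.26, 6.6e-05, adjusted p = 0.35 with an estimated correlation), integrated stress response genes (0.28, 6.6e-05, adjusted p = 0.35 with an estimated correlation; 2 higher adjusted over the list alone) and DNA replication genes (0.23, 0.000317, adjusted p = 0.442 with an estimated correlation) were higher, with 0 members called. With the block 1 integrated stress response gene was called higher, and without the untreated WT unit b 3. Estrogen receptor targets (3 higher and 5 lower adjusted over the list alone; median -0.01, mean 0.17, 0.94), luminal (1 lower adjusted over the list alone; -0.07, 0.475), basal (1 lower, ACTA2; -0.02, 0.2), cholesterol synthesis (-0.03, 0.94), unfolded protein response (0.01, 0.94), interferon (1 higher adjusted over the list alone; 0.07, 0.847), lysosome (-0.10, 0.475), hypoxia and glycolysis (0.18, 0.374), chromatin (0.05, 0.608), fibroblast (1 higher adjusted over the list alone; median -0.18, mean 0.30, 0.475) and ribosomal protein (0.01, lower by camera, 0.955) lists did not pass.

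Under tamoxifen edgeR called 46 of 10037 genes between KO and WT (15 higher and 31 lower; 858 at an unadjusted p under 0.05), DESeq2 101, limma-voom 41 and edgeR with a replicate block 91 (30 higher and 61 lower). The deposited comparison held 108, with all 46. The units did not overlap for 17% of genes, against 10% by chance. Without the untreated WT unit b there were 167 calls (62 higher and 105 lower, all 46 kept). Without the treated WT units a, b and D there were 29, 20 and 27, and without the treated KO units a, b and D 27, 16 and 23. Of 14 named calls 6 ended in at least 1 of these fits, among them TP53 without the treated KO units b (edgeR adjusted p = 0.0647) and D (0.0577), while CDKN1A passed in every such fit.

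**Figure D3:**
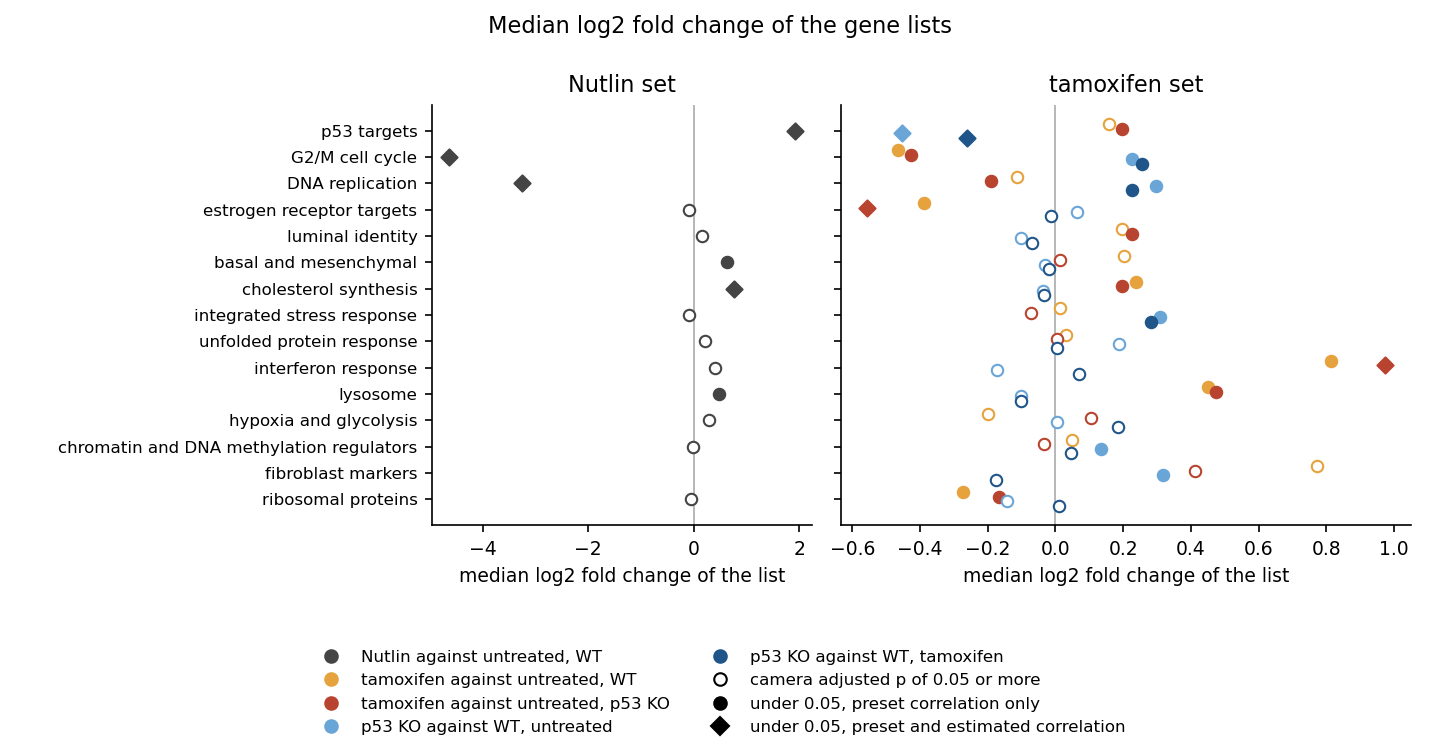
Median log2 fold change of 15 gene lists in each comparison, with open circles for lists that did not pass, filled circles for those that passed at the preset correlation alone and diamonds for those that also passed with an estimated one. The p53 targets move to 1.92 with Nutlin and to -0.45 and -0.26 in KO cells, and the interferon genes to 0.82 and 0.97 with tamoxifen.

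Whether the tamoxifen response differs between KO and WT cells was tested by the interaction term. CDKN1A was 1.92-fold higher with tamoxifen in KO and 1.27-fold in WT, neither past the threshold in the main fit. With the replicate block, the rise in KO passed (edgeR adjusted p = 0.00308). The difference of the responses did not pass for CDKN1A (log2 0.60, SE 0.338, edgeR adjusted p = 1.00), nor for TP53 (-0.22), MDM2 (-0.01), ESR1 (0.40) and GATA3 (0.22). edgeR called 0 of 10037 genes (228 at an unadjusted p under 0.05) and DESeq2 0. On simulated data without series or letter effects, edgeR found 19% of 2-fold and 96% of 4-fold differences of this kind. These shares hold for genes with a mean of at least 20 CPM, which MDM2 and ESR1 did not reach in this set. Interferon genes (median 0.19) and p53 targets (0.17) did not pass (camera adjusted p = 0.0948 for both), but p53 targets did without the untreated WT unit b at the preset correlation (0.00203). With an estimated correlation, which was run only with all units, they did not pass (adjusted p = 0.386). None of the other lists passed, and for G2/M genes (median -0.01, mean 0.14), DNA replication (-0.05, 0.03) and estrogen receptor targets (-0.05, 0.15) the median and mean differed in sign.

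Fold changes were then compared between comparisons that share no library. As a set, the 2070 tested genes higher with Nutlin were shifted lower in untreated KO cells (median log2 -0.15 against -0.02 for all genes, 66.1% below 0, 29 called lower and 1 higher; camera adjusted p = 5.1e-06, and 0.0229 with an estimated correlation) and in KO cells under tamoxifen (-0.12; 1.4e-06, and 0.0229 with an estimated correlation). The shift in untreated KO cells was smaller without the untreated WT unit b (median -0.06 against 0.01 for all genes, 58.4% below 0, camera adjusted p = 0.000445). The set of 2082 genes lower with Nutlin was shifted higher in untreated KO cells (median 0.06, camera adjusted p = 0.000975, and 0.15 with an estimated correlation). Under tamoxifen the set did not pass (0.04, 0.0508, and 0.373 with an estimated correlation), though it did at the preset correlation without the untreated WT unit b (0.0240). Its genes at least 2-fold lower with Nutlin passed under tamoxifen (0.10; 0.00650, adjusted p = 0.295 with an estimated correlation). Of 45 genes lower in untreated KO cells and tested in both sets, 29 were higher with Nutlin, against 12 by chance (Fisher's exact test, adjusted p = 3.0e-07), and 14 of 27 under tamoxifen, against 7.22 (0.0111). The rank correlation of the Nutlin fold changes with those of KO was -0.24 across 7737 genes in untreated cells (jackknife SE 0.112) and -0.23 under tamoxifen (SE 0.092). Both KO comparisons had a rank correlation of 0.45 (SE 0.119) and shared 26 lower genes, TNFRSF10C, KLK11 and CDKN1A among them, against 0.158 by chance, and 3 higher genes (WNT6, SCIN and, named after its value was seen, MT1F), against 0.012. Any lasting difference between the KO and WT cells would be shared in this way, so the sharing does not test p53 as its cause.

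As sets, the Nutlin genes moved in the same direction with tamoxifen in WT and KO cells. The set higher with Nutlin was shifted higher with tamoxifen in WT (median 0.18; camera adjusted p = 1.5e-09, and 0.0212 with an estimated correlation) and in KO (0.20; 4.2e-11, and 0.0212 with an estimated correlation). The set lower with Nutlin was shifted lower in WT (-0.20; 2.5e-09, and 0.0334 with an estimated correlation) and in KO (-0.19; 2.6e-15, and 0.0212 with an estimated correlation). Of 39 genes higher with tamoxifen in WT, 20 were higher with Nutlin, against 10.4 by chance (Fisher's exact test, adjusted p = 0.00272), and of 93 in KO 55, against 24.9 (1.4e-10). Of 22 lower in WT 19 were lower with Nutlin, against 5.92 (2.2e-08), and of 29 in KO 23, against 7.80 (1.5e-08). The rank correlation with Nutlin was 0.38 in WT (SE 0.155; 0.242 without the untreated WT unit a and 0.437 without unit b) and 0.47 in KO (SE 0.0605). The tamoxifen responses of WT and KO had a rank correlation of 0.56 (SE 0.151) and shared 31 higher genes, BCAS1, OAS1, IFIT3 and AGR2 among them, against 0.533 by chance, and 19 lower genes, GREB1, TFF1 and CXCL12 among them, against 0.0921.

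**Figure D4:**
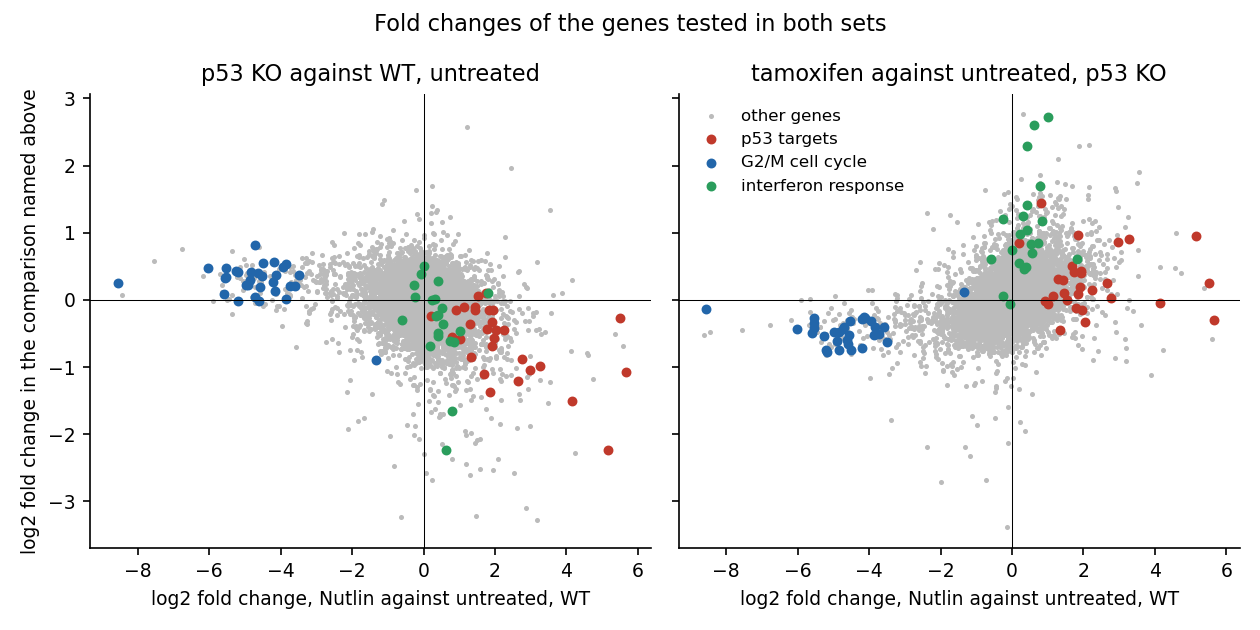
Log2 fold change with Nutlin (x axis) against that of KO in untreated cells and that of tamoxifen in KO cells (y axes), 1 point per gene, with p53 targets, G2/M genes and interferon genes coloured. The rank correlation across genes is -0.24 for the former and 0.47 for the latter.

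Few markers of other cell types were measured. COL3A1, a fibroblast collagen, was the highest fibroblast marker at 14 CPM in the Nutlin set and 41.9 CPM in the tamoxifen set, and CD68, a macrophage protein that epithelial cells also express, the highest leukocyte marker at 27.1 and 11 CPM. ITGB4, an integrin, was the highest basal gene at 270 and 348 CPM. Too few markers were measured to test the fibroblast list with Nutlin (1 gene) or the leukocyte list (1 gene with Nutlin, CD68, which was higher; 2 genes in the tamoxifen set). The tables held 0 mitochondrially encoded transcripts.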

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

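The tests of a wrong label for unit b and for each of its libraries were chosen only after the result was seen, as were the values without this unit for the gene sets, and the idea of a GC trend came from the names of the genes high in it. In groups of 4 or 5 libraries, 88 sets of values (22 measures in each of 4 groups) were searched for a library far from the others of its group, and 9 were found. Chance flags about 1 in 20 groups, or 4.40 of 88, and libraries that share a name stem are not independent.

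The library labelled untreated WT replicate 4, with 129204 counts, lay far below the other untreated WT libraries in 5 measures. In it 6820 genes were detected (next lowest 11120), and GATA3 had 301 CPM (1139). The mean log2 CPM was 5.168 for p53 targets (5.949), 7.315 for luminal genes (8.024) and 4.412 for basal and mesenchymal genes (5.44). Fewer genes detected follows from 129204 counts, and at this depth the mean log2 CPM of a list also depends on the genes at 0.

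Other libraries far from their group were of ordinary depth. In WT cells under tamoxifen, replicate 4, of series ED, was highest in DNA replication genes such as MCM7 and TK1 (mean log2 CPM 6.374, next 6.126), and replicate 2 lowest in chromatin regulators (5.863, next 5.896). In KO cells under tamoxifen, replicate 4, also of series ED, was highest in cholesterol synthesis genes (7.712, next 7.313) and in hypoxia and glycolysis genes (7.443, next 7.148). Series is a covariate of the fits. No explanation of these values was tested.

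A difference between WT and KO in the response to tamoxifen was seen in the genes at least 2-fold lower with Nutlin. Their median log2 difference was -0.03338 (camera adjusted p = 0.01805), that is, a slightly lower value in KO. It did not pass with an estimated correlation (adjusted p = 0.347) or without the untreated WT unit b (0.658). The set of all genes lower with Nutlin did not pass (0.0907).

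The untreated WT unit b, which holds the library above, had a mean correlation with the other units of 0.880, against at least 0.945 for each other unit. Depth alone is argued against, since the other units thinned to its 1019457 counts kept at least 0.9399 (SD 0.00717). GC content was taken from the end of the longest annotated transcript of each gene. With length it carried 39.1% of the variance of the deviation of unit b (correlation with GC content 0.613). Removing these trends brought unit b to 0.9093, still below the lowest other unit (0.949, SD 0.00611). Trends on these measures are thus a part and not the whole. The measures may miss the transcript ends that these cells use, and depth was not removed together with them, so a larger part stays possible. A wrong label of unit b is argued against by its median place between KO (0) and the other WT units (1) of 1.26 (95% interval 0.831 to 1.37, 46 genes) and between tamoxifen (0) and untreated (1) of 0.768 (0.634 to 1.04, 140 genes), and one of its replicate 3 alone (mean correlation 0.89) by 1.08 (0.831 to 1.33) and 0.8 (0.607 to 0.949). A wrong label of replicate 4 alone stays open, since its interval between KO and WT was wide (1.11, 0.257 to 1.27). Its CDKN1A level of 154 CPM lay between the untreated (74.2 to 122) and the treated KO libraries (160 to 231). Its place between tamoxifen (0) and untreated (1) was 1.62 (1.18 to 1.91), past the untreated end. Degraded or scarce RNA, a sample from elsewhere, a difference of the culture and any biological explanation were not tested.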

How the results depend on the processing

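Chosen only after the data were seen were the fit without the untreated WT unit b with a replicate block, the removal of the library with the fewest counts, the values without that unit for lists and Nutlin sets, and the leave-one-out of the correlations; all other settings were chosen before. Counts are given in the order KO against WT untreated, tamoxifen in WT, tamoxifen in KO and KO against WT under tamoxifen, where the reported ones are 59, 78, 140 and 46.

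With Nutlin, CDKN1A, MDM2, TP53 and the other 40 called named genes kept their direction and call in every alternative. The 4213 calls became 4206 with RLE scaling, 3325 with DESeq2, 4569 without a filter and 4069 with a replicate block (4041 kept), and 3702 to 4057 with 1 library left out.

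In the tamoxifen set no called named gene reversed in any setting. Over all comparisons, Nutlin included, and all settings other than leave-one-out, the calls of named genes held 803 times and were lost 89 times, mostly with series EA alone, where each group has 2 units. With 1 unit left out they held 870 times and were lost 108 times. CDKN1A stayed lower in KO and passed in every setting except series EA alone (edgeR adjusted p = 0.0755 untreated and 0.131 under tamoxifen).

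Counts stayed within 1.5 times the reported ones with RLE scaling (56, 52, 121 and 45), without a filter (60, 72, 135 and 54) and without the library with the fewest counts (65, 97, 153 and 51). Without the series covariate there were 54, 43, 108 and 46, and with limma-voom 36, 51, 95 and 41. DESeq2 gave 125, 284, 260 and 101. The 17 libraries as separate samples gave 145, 497, 274 and 78 with the run, as read from the names, as a covariate and 195, 639, 277 and 119 with a block by replicate number, settings that count libraries of a shared stem as independent. Series EA alone gave 4, 1, 2 and 0 (2 units per group), and the groups of a comparison alone gave 7, 3, 446 and 78. Leaving out 1 unit gave 11 to 94, 10 to 491, 20 to 462 and 16 to 167, with the highest counts each time without the untreated WT unit b. For the difference of the tamoxifen response, 0 genes were called in every setting that could be fitted, leave-one-out included (0 to 0); the groups of a comparison alone cannot give it.

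A replicate block by letter gave 106 (23 higher and 83 lower), 243 (153 and 90), 286 (206 and 80) and 91 (30 and 61) calls and kept all 59, 78, 140 and 46. The letters were taken to pair the units only for tamoxifen in KO and for KO under tamoxifen, where every same-letter correlation was at least 0.249. Without the untreated WT unit b and with the block there were 371, 1521, 1481 and 737. CDKN1A with tamoxifen in KO cells (log2 0.94, edgeR adjusted p = 0.0735) passed with the block (0.00308), with DESeq2 (0.0155), with its groups alone (0.0103), without the untreated WT units a (0.0461) and b (0.0160), and without unit b with the block (7.7e-06). In that last fit TP53 (log2 -0.56, edgeR adjusted p = 0.0133) and GATA3 (0.42, 0.00615) passed with tamoxifen in KO, and CDKN1A (0.34, 0.0451) and TP53 (-0.43, 0.0379) in WT.

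Some genes that were not called changed sign, none past the threshold. GATA3 in KO against WT untreated (log2 -0.05) was 0.00599 without a filter, 0.117 and 0.277 with 17 libraries (run, block), 0.0340 with limma-voom and 0.0880 with series EA alone, and -0.127 to 0.0422 with 1 unit left out. ESR1 with tamoxifen in KO (-0.08) was 0.0318 and 0.0689 with 17 libraries and 0.369 with series EA alone, and -0.493 to 0.327 with 1 unit left out. ESR1 with tamoxifen in WT was -0.923 to 0.0503 with 1 unit left out (highest without the untreated unit a), and ESR1 in KO against WT under tamoxifen 0.0573 with series EA alone. MDM2 with tamoxifen in KO was 0.00360 with series EA alone and -0.594 to 0.0509 with 1 unit left out (highest without the untreated KO unit D). For the difference of the responses, MDM2 (-0.01) was 0.00469 with the block, 0.0564 with limma-voom, 0.141 with series EA alone, 0.159 without unit b and with the block, and -0.298 to 0.346 with 1 unit left out. GATA3 was -0.0742 and -0.137 with 17 libraries, and ESR1 -0.121 to 0.871 with 1 unit left out. The cause was not tested.

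With an estimated correlation, camera called 1, 0, 2 and 1 lists in place of 6, 6, 9 and 4, and 4 in place of 6 with Nutlin. The p53 targets kept their call with Nutlin and in both KO comparisons, and the interferon genes and estrogen receptor targets theirs with tamoxifen in KO. With RLE scaling cholesterol synthesis in WT lost its call (camera adjusted p = 0.0603), and without the series covariate the fibroblast list of untreated KO cells did (0.102). Without the untreated WT unit b, chromatin regulators in untreated KO cells lost theirs (0.304), luminal genes in untreated KO cells (0.0408) and DNA replication with tamoxifen in WT (0.000959) passed, and 1 list, p53 targets (0.00203; adjusted p = 0.386 with an estimated correlation and all units), passed for the difference of the responses. With the block as well these 4 changes held, and interferon genes in untreated KO cells passed (0.0323).

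Lists that changed direction did not pass in either fit. With the block this was ribosomal proteins in KO under tamoxifen (camera adjusted p = 0.973). The others, without the untreated WT unit b, were estrogen receptor targets (0.469), cholesterol synthesis (0.184), lysosome (0.396) and ribosomal proteins (0.937) in untreated KO cells, chromatin regulators with tamoxifen in WT (0.594), basal genes with tamoxifen in KO (0.865) and ribosomal proteins in KO under tamoxifen (0.867). For the difference of the responses they were G2/M (0.247), DNA replication (0.376), estrogen receptor targets (0.509), cholesterol synthesis (0.119) and ribosomal proteins (0.984). With the block as well, all of these but lysosome changed direction, and so did the unfolded protein response (untreated KO, tamoxifen in WT, difference), hypoxia and glycolysis with tamoxifen in KO, interferon genes in KO under tamoxifen and the integrated stress response for the difference. The cause was not tested.

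The genes lower with Nutlin lost their call in untreated KO cells with an estimated correlation (camera adjusted p = 0.150). In KO under tamoxifen they passed with a 2-fold threshold for the Nutlin genes (0.00650, adjusted p = 0.295 with an estimated correlation) and without the untreated WT unit b (0.0240). For the difference of the responses they passed with the 2-fold threshold (0.0181), but not with an estimated correlation (0.347) or without unit b (0.658), and the genes higher with Nutlin changed direction without unit b (0.115). The rank correlation of both KO comparisons rose from 0.45 to 0.594 over genes of at least 20 CPM. With 1 unit left out it was 0.357 to 0.497, and the correlation of Nutlin with tamoxifen in KO 0.421 to 0.471. That of Nutlin with tamoxifen in WT (0.38) was 0.242 to 0.437, lowest without the untreated WT unit a. That of Nutlin with KO was -0.306 to -0.184 in untreated cells and -0.276 to -0.166 under tamoxifen, and that of both tamoxifen responses 0.441 to 0.580. The cause was not tested.

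Depth limits the untreated WT unit b most, with 1019457 counts, and genes of few counts in the tamoxifen set such as MDM2 and ESR1.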

Other observations

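The test of p53 status or tamoxifen on the immediate-early genes and the test of p53 activation by tamoxifen were chosen only after the result was seen, and the immediate-early list itself was written after several of its genes had been seen low in b units.

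Immediate-early genes, which respond within minutes to growth factors and stress, were low in the units with the letter b. EGR1, a zinc-finger transcription factor on chromosome 5 (138465490 to 138469315), had 30.3 ± 18.6 CPM in the 4 b units and 402 ± 83.1 CPM in the other 8, and FOS 3.79 ± 1.30 and 82.7 ± 30.9 CPM. NR4A1 had 19.7 and 83.1 CPM and DUSP1 23.2 and 89.4 CPM. Of 15 measured genes of a list of 24, 8 were lower in every b unit than in every other unit. They include JUN, IER2, ZFP36 and KLF10.

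Among libraries without a date in their name, the median log2 difference between b and a was -1.07, -0.694 and -0.793 in the untreated WT, untreated KO and treated KO groups. This does not settle the sequencing run as a cause, since the labels do not say that undated libraries share a run and treated WT cells have no undated a library, so the run stays open. The median difference of unit b from the other units of its group was -1.07, -1.06, -0.641 and -0.825 in the 4 groups. The units of a group share p53 status and treatment, so a difference within all 4 groups argues against either, as labelled, as its cause. A candidate explanation is the time or handling of the cells at harvest, which the labels do not give and which was not tested.

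Tamoxifen and Nutlin fold changes went together across genes in KO cells, where the rank correlation was 0.4683 (jackknife SE 0.0605), although genes are not independent replicates. The shared fall of the cell-cycle lists and of the genes at least 2-fold lower with Nutlin is not the whole of it. Without these genes, 0.4024 remained over the 6951 genes left. Genes lower with Nutlin by less than 2-fold stayed in, so a shared slowing of the cell cycle that moves further genes stays open. A shared trend with expression level, or with GC content or length as measured for unit b, is argued against as the whole cause, since 0.436 remained after its removal (98.6% of the genes had GC content and length). Activation of p53 by tamoxifen lacks support in WT cells, where the p53 targets did not pass as a list (median log2 0.16, camera adjusted p = 0.522, against 1.92 with Nutlin). Of 29 targets 0 were called, but only 78 of 10037 genes were called at all. MDM2, of few counts, had a log2 of -0.29. CDKN1A passed only without the untreated WT unit b and with the block (log2 0.343, edgeR adjusted p = 0.0451). In KO cells the p53 targets were higher with tamoxifen at the preset correlation alone. These values do not exclude activation of p53 in WT cells. If p53 activation were the cause, the correlation would be higher in WT than in KO cells. It was not (0.382, SE 0.155, in WT), but the SE is too wide for this to decide. In KO cells p53 activation would need p53 that the labels call absent, and whether some remains was not tested. Culture time, solvent and cell density were not tested either and stay open.

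For each comparison of 3 units against 3, the 10 possible splits are too few for a share under 0.05, and 1 of 10 splits, the real one, gave as many genes. With Nutlin the real split gave 4213 genes, and the highest other split gave 0. For KO against WT it gave 59 (highest other 2) in untreated cells and 46 (0) under tamoxifen, and for tamoxifen 78 (10) in WT and 140 (0) in KO. For tamoxifen in KO and for KO under tamoxifen, where the letters pair the units, the other splits that part every pair gave 0, and the remaining splits put both units of a letter on 1 side. For the difference of the tamoxifen response, 100 of 100 splits gave as many as the 0 genes called, with 3 in the highest. With 0 genes called every split gives as many, so the splits say nothing about this difference.

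Beyond the named genes, the lower genes of untreated KO cells included, chosen after their values were seen, CCK, a peptide hormone (log2 -3.28, edgeR adjusted p = 0.00647), and KRT15, a basal keratin (log2 -1.69, edgeR adjusted p = 0.0242). Under tamoxifen CCK (log2 -3.22, edgeR adjusted p = 0.0191) and KRT15 (log2 -1.44, edgeR adjusted p = 0.0438) were lower too. GATA4, a transcription factor, was lower with tamoxifen in WT cells (log2 -4.04, edgeR adjusted p = 0.000386) and higher in KO than in WT under tamoxifen (log2 2.62, edgeR adjusted p = 0.0337). In both comparisons GATA4 missed the rule for named genes, which asks for at least 10 CPM in the higher group and no overlap between units. It was lower with tamoxifen in KO cells as well, and the difference of the responses was called for 0 of 10037 genes.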
